A study of Mus musculus with 6 samples.

How the data were processed

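Single-cell RNA was measured in livers of wild-type male mice with the BD Rhapsody whole transcriptome assay, per the labels. There were 6 libraries, 3 from mice given vehicle (DMSO) and 3 from mice given CWHM-12, an inhibitor of all integrins with the αV subunit. The labels give a batch for each library. Batch 2024.6 holds DMSO 1, DMSO 2 and CWHM-12 1, and batch 2024.12 holds DMSO 3, CWHM-12 2 and CWHM-12 3. The labels give each library as a sample from a mouse but print no mouse identifier, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries shared more than 5 of their 10000 barcodes.

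The deposited values are whole-number counts of molecules (UMIs) per gene and barcode, per the file headers, and each library holds 10000 barcodes. The genome build was GRCm39, per the submitters' processing notes. The aligner, the annotation release and the way barcodes were selected are not given in the sources used here. The deposited files name genes by symbol, or by Ensembl identifier where there is none, and no coordinates were used. The reference available was of build GRCm38 (GENCODE vM21), so it served only for the GC content of transcripts, matched by symbol.

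A barcode was kept as a cell with at least 300 genes, at least 500 UMIs and at most 30% mitochondrial UMIs, which left 38697 cells. Doublets were scored in each library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0.474% of the cells of CWHM-12 2, which is low for that many cells, so a common score of 0.25, chosen after these thresholds were seen, was used in all libraries instead. This removed 705 cells, between 1.14% and 2.66% of a library, and left 37992. Cells were clustered on 2000 variable genes, 40 principal components and 20 neighbours with the Leiden algorithm at a resolution of 1.5 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). The libraries were not integrated. Of 44 clusters, 36 were named by hand as 1 of 16 classes from fixed markers and their leading genes, and 8 stayed unnamed. The unnamed clusters include cluster 13 (1133 cells), which scored highest for Kupffer cells, and clusters 23 and 24 (369 and 353 cells), which scored highest for stellate cells. Each named cluster scored highest for its own class except cluster 18, named LSEC from Lyve1 and Esm1 among its leading genes, which scored highest for erythroid genes (3.085 against 1.114). A class name in this text means cells that resemble the named type by these markers.

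Raw counts were summed over the cells of a class in each library, leaving out libraries with fewer than 20 cells of the class. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The fit used TMM normalization, the filter on low counts of edgeR, a batch term and the Benjamini-Hochberg adjustment at 0.05 within a class. Levels are CPM on TMM-scaled library sizes, given as the mean ± SD of 3 libraries. Fold changes are log2 of CWHM-12 over DMSO. Their standard errors (SE) were worked back from the test, as the size of the fold change over the square root of the F statistic. Values within a batch are differences of mean log2 CPM with a prior count of 2. Portal fibroblasts and basophils had too few cells, so 14 classes were tested. In all, 39 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation (limma 3.58.1), where at least 5 genes of a list were tested in a class. Whether LSEC and stellate cells responded differently was tested as the interaction of class and treatment with the library as a block. This fit held no term for a difference between the classes that goes with batch. Shares of cells were compared with an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1. Hepatocytes stayed out of the denominator because the preparation sets their number, and no cluster was named erythroid.

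The groups, tests, gene lists, markers, cell filter and rule for named genes were fixed before the data were examined. The rule names, in each of 5 main classes, up to 8 genes with the largest rise and 8 with the largest fall among those that pass with at least 20 CPM. Where fewer than 5 pass, it also names the 5 of smallest p with at least 20 CPM, as values that did not pass. It adds the αV subunit and its β partners where tested, and the 3 members of smallest p of each list that passes. Not all genes named by the rule are described in the text. Genes named outside the rule are said to be chosen after their values were seen. Alternatives were fits without the batch term, with the replicate number as a block, with DESeq2 1.42.0, with limma voom and sample weights, with the size factors of DESeq2, without the filter on low counts, and without each library in turn. Others were a looser cell filter (200 genes, 300 UMIs, 50% mitochondrial), a stricter one (500 genes, 1000 UMIs, 15%), doublets kept, classes from marker scores alone and equal cell numbers. Offsets for GC content and a fit without barcodes of 10 or more haemoglobin UMIs were added after seeing the data.

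The tests were tested on simulated data with the means, library sizes and spread of each class and 200 changed genes. With log2 changes of 2, the fit recovered 86% of the higher and 72% of the lower genes in LSEC, 100% and 78% in stellate cells, 88% and 80% in Kupffer cells, 86% and 62% in monocytes and 74% and 64% in hepatocytes. With log2 changes of 1, it recovered 12% and 10% in LSEC, 34% and 28% in stellate cells, 32% and 12% in Kupffer cells, 10% and 4% in monocytes and 6% and 2% in hepatocytes. A gene that changed 2-fold was thus missed more often than found in these classes. Camera called 2 of 2 simulated lists shifted by 0.5 and 0 of 18 unshifted lists in each of these 5 classes. These lists had no correlation between genes.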

Results

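Single-cell transcriptomes were collected from livers of mice after partial ligation of the inferior vena cava (pIVCL), an operation that congests the liver. The mice were 8 to 10 weeks old at surgery. After 2 weeks they received osmotic pumps with DMSO or with CWHM-12 at 100 mg/kg/day, and livers were taken after 4 weeks of treatment. Integrins with the αV subunit bind matrix proteins and release active TGF-β from its latent form, and the comparison asks which liver cells differ when they are inhibited in the congested liver. The 3 DMSO libraries held 30836277, 28220477 and 44557538 UMIs and the 3 CWHM-12 libraries 31294555, 40382504 and 48100436. About 10000 viable cells were used for each library, per the labels, each file holds 10000 barcodes, and the cell filter left 5934, 3163 and 6897 cells in DMSO 1 to 3 and 6182, 8447 and 8074 in CWHM-12 1 to 3. DMSO 2 lost most, since 5867 of its barcodes had fewer than 300 genes, with a median of 85.8% mitochondrial UMIs.

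Liver sinusoidal endothelial cells (LSEC), the fenestrated lining of the sinusoids, and Kupffer cells, the resident macrophages, were the most numerous nonparenchymal classes. LSEC made up 27.4% ± 3.29 of the kept cells without hepatocytes in DMSO libraries and 40.1% ± 14.8 in CWHM-12 libraries (SD, n = 3 each). The difference had opposite signs within the batches, -4.97 points in batch 2024.6 and 24.3 points in batch 2024.12, and an exact permutation p of 0.3. Cholangiocytes, the cells of the bile ducts, made up 3.59% ± 0.879 and 2.05% ± 0.562, with differences of -1.69 and -2.095 points within the batches (exact permutation p = 0.1, the smallest possible here, 0.711 after adjustment over 16 classes). B cells made up 13.95% ± 1.13 and 6.78% ± 7.23, with differences of 1.68 and -12.6 points within the batches. Stellate cells, the matrix-producing pericytes of the sinusoids, made up 7.63% ± 3.40 and 6.26% ± 0.543, and Kupffer cells 20.1% ± 2.74 and 21.6% ± 6.10. Unnamed clusters held 9.21% of these cells in both groups. No share passed, and this test, which ignores batch, could not reach a p under 0.1. The Wilson 95% interval of a share in a single library extended at most 1.74 points to either side, for counting error only. Hepatocytes, which the preparation aimed to bring to 10%, made up 25.1%, 14.97% and 25.6% of kept cells in DMSO 1 to 3 and 45.2%, 3.17% and 24.04% in CWHM-12 1 to 3.

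**Figure D1:**
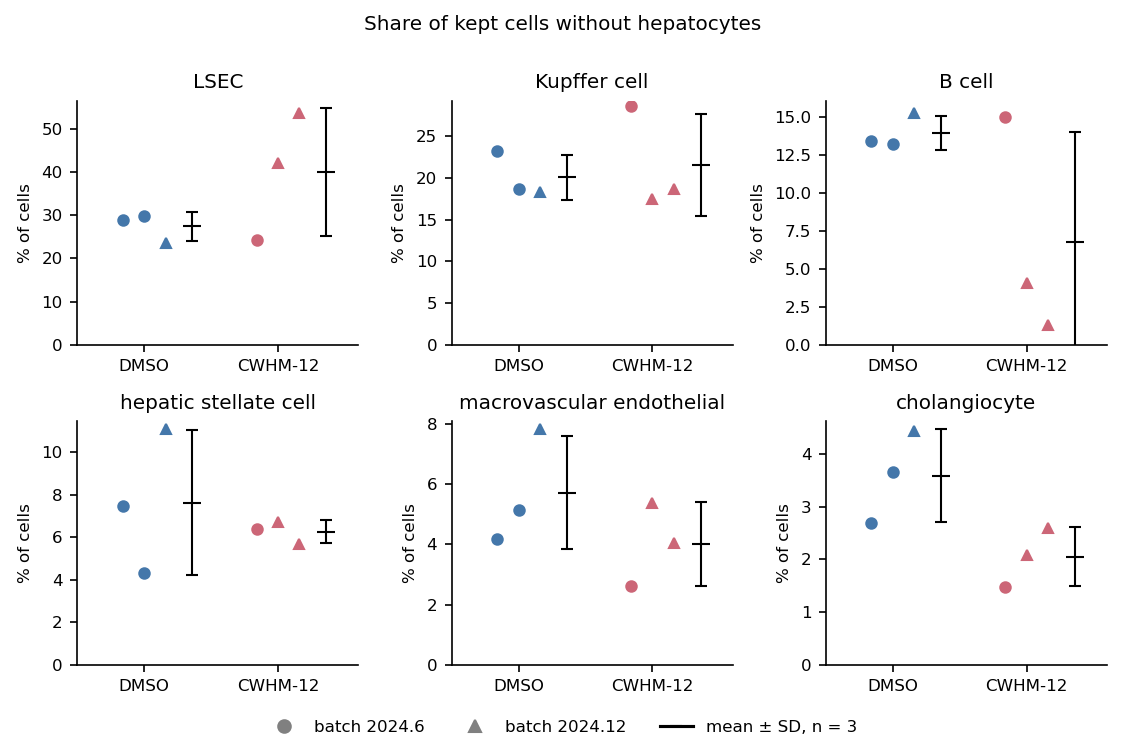
Share of kept cells without hepatocytes (y axis, percent) for 6 classes in the DMSO and CWHM-12 groups; circles are libraries of batch 2024.6, triangles those of batch 2024.12, and black marks the mean ± SD of 3 libraries. LSEC of CWHM-12 2 and CWHM-12 3, at 42.2% and 53.7%, lie above the other 4 libraries, while CWHM-12 1 lies at 24.3%.

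In LSEC, genes that respond to blood flow and stretch were higher under CWHM-12 as a group, and targets of the mechanosensitive co-activators YAP and TAZ were lower. Of 15 measured genes of the flow and stretch list, 14 had a positive log2 fold change, with a median of 0.25 (0.29 and 0.12 within the batches; camera, adjusted p = 0.00932, and adjusted p = 0.805 with an estimated correlation). Klf2, a transcription factor induced by laminar shear, stood at 292 ± 103 CPM in DMSO and 754 ± 412 CPM in CWHM-12 (log2 1.05, SE 0.30), and Thbd, the anticoagulant receptor thrombomodulin, at 1.09 on the log2 scale (SE 0.47). Edn1, the vasoconstrictor endothelin-1 and a member of the same list, went the other way at -1.47 (SE 0.61). The flow and stretch list shares Egr1 and Atf3 with a list of dissociation and early response genes, which also rose in LSEC. It passed in 4 of 14 classes, Kupffer cells and cholangiocytes among them, so it is not particular to endothelium. Of 15 YAP and TAZ targets, 10 were negative, with a median of -0.18 (-0.085 and -0.57 within the batches; adjusted p = 0.00932, and adjusted p = 0.805 with an estimated correlation). Ajuba, a LIM domain protein of the Hippo pathway, stood at 74.8 ± 23.7 and 27.5 ± 14.9 CPM (log2 -1.45, SE 0.46), and Ccn1, a matricellular protein, at 66.0 ± 49.7 and 23.4 ± 7.58 CPM. Collagens and matrix proteins were lower in 12 of 15 measured genes, with a median of -0.27 (adjusted p = 0.0271, and adjusted p = 0.805 with an estimated correlation). The call was kept in 8 of 16 alternatives. Of its members, Sparc stood at 2767 ± 353 and 2192 ± 202 CPM. Col6a3, at 11.3 ± 6.04 and 4.17 ± 3.24 CPM, had a log2 fold change of -1.03 and Col5a2 one of 1.16. Among genes that did not pass, Rasd1, a small GTPase, stood at 10.9 ± 2.98 and 54.4 ± 34.2 CPM and the tetraspanin Cd63 at 39.9 ± 5.30 and 14.6 ± 8.54 CPM.

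Of the other lists, 3 passed in LSEC. The list of dissociation and early response genes rose, with 16 of 18 members positive and a median of 0.38 (adjusted p = 0.805 with an estimated correlation), including Socs3 (log2 0.82) and Jund (0.43); enzymatic dissociation of tissue also induces these genes. Transcripts of erythroid cells rose with a median of 2.01 over 5 genes, and genes of periportal hepatocytes with a median of 0.90 over 12 (adjusted p = 0.805 with an estimated correlation for both). These are transcripts of other cell types. The hepatocyte transcript Mup20, not a member of these lists, went the other way without passing, at 363 ± 175 and 147 ± 83.6 CPM. In LSEC of CWHM-12 1, 95.9% of 12741 haemoglobin UMIs lay in 5 barcodes, and in DMSO 1, 94.6% of 8290 lay in 11. The erythroid list had a median of 0.027 with the looser cell filter and -0.11 with classes from marker scores alone, and passed in neither. In the 6 lists that passed in LSEC, 0 genes passed when adjusted over the list alone. Lists that did not pass include the TGF-β response (10 of 19 positive, median 0.0011, mean -0.065, adjusted p = 0.459), LSEC identity (median 0.11, adjusted p = 0.378) and endothelial capillarization, the loss of the sinusoidal phenotype (median -0.16, adjusted p = 0.324). The target itself, Itgav, stood at 13.5 ± 2.01 and 13.99 ± 2.63 CPM. Over all 11597 genes, edgeR called 0, with 237 at an unadjusted p under 0.05. DESeq2 called 3, Rasd1, Capn11 and Fbln2, and limma voom 0. Fbln2, a matrix protein of larger vessels, stood at 30.9 ± 13.7 and 5.23 ± 3.02 CPM, and it and Capn11 were chosen after their values were seen. The cluster with the largest part of LSEC differed between libraries: cluster 5 held 44.5%, 55.6% and 39.2% in DMSO 1 to 3 and 49.1%, 4.08% and 0.405% in CWHM-12 1 to 3, and cluster 6 held 44.01% in CWHM-12 3. Clusters 7 and 8 held 28.3% and 30.8% in CWHM-12 2 and 10.9% and 13.06% in CWHM-12 3, but also 22.5% and 11.5% in DMSO 3. Cluster 19 held 29.2%, 23.04% and 23.8% in DMSO 1, DMSO 2 and CWHM-12 1 and 2.27% in DMSO 3. Cluster 5 has Ccn2, a member of the YAP and TAZ list, among its leading genes. Whether the lists in LSEC moved through this mix of clusters was not tested. The mitochondrial share of UMIs, a sign of cell quality, also went with the groups in LSEC, at 9.15%, 11.2% and 9.01% in DMSO 1 to 3 and 8.11%, 7.78% and 8.79% in CWHM-12 1 to 3.

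**Figure D2:**
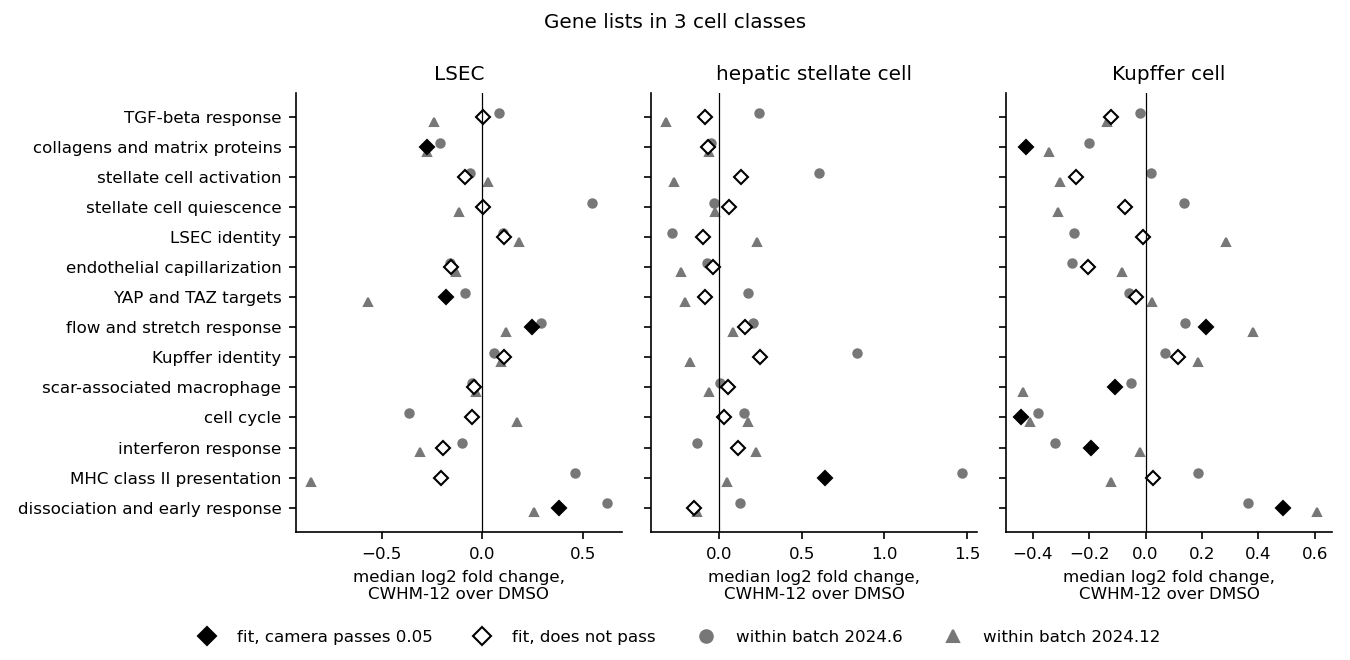
Median log2 fold change of CWHM-12 over DMSO (x axis) for 14 gene lists in LSEC, hepatic stellate cells and Kupffer cells; diamonds give the fit over both batches, filled where camera with its preset correlation passed, and grey circles and triangles the medians within each batch. The TGF-β response lies at 0.0011, -0.087 and -0.12 in the 3 classes and passes in none.

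In hepatic stellate cells, the genes of matrix production, activation and TGF-β signalling showed no shift that passed. Collagens and matrix proteins had a median log2 fold change of -0.067 over 23 genes (adjusted p = 0.763), the activation list 0.13 over 15 genes (adjusted p = 0.901), the quiescence list 0.056 over 19 (adjusted p = 0.763) and the TGF-β response -0.087 over 22 genes (mean 0.011, adjusted p = 0.763). Itgav stood at 181 ± 21.2 and 173 ± 51.5 CPM, and Itgb3, which pairs with it in the vitronectin receptor, at 240 ± 28.01 and 334 ± 92.6 CPM (log2 0.57, SE 0.23, edgeR adjusted p = 1.00). Among genes that did not pass, the receptor Adcyap1r1 stood at 45.9 ± 12.4 and 87.5 ± 8.18 CPM and the basement membrane collagen Col18a1 at 13.7 ± 7.12 and 27.2 ± 9.02 CPM. Thsd7a stood at 67.8 ± 19.9 and 26.8 ± 10.8 CPM, and Adamtsl2, a secreted matrix protein, at 87.7 ± 54.4 and 42.1 ± 11.95 CPM.

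In all, 4 lists rose in stellate cells. Genes of antigen presentation by MHC class II were positive in 5 of 5, with a median of 0.64 (1.47 and 0.044 within the batches; adjusted p = 1.02e-05, and adjusted p = 0.881 with an estimated correlation), but the median was -0.17 with classes from marker scores alone. H2-Ab1 stood at 44.9 ± 17.4 and 103 ± 6.22 CPM, and H2-Eb1 with it passed when adjusted over the list alone. Both genes and H2-Aa are also among the leading genes of the unnamed cluster 22. Whether these transcripts came from other cells was not tested. The NF-κB response was positive in 11 of 12 genes (median 0.24, adjusted p = 0.00794, and adjusted p = 0.881 with an estimated correlation), with Relb at 7.88 ± 3.63 and 21.8 ± 2.72 CPM. The other 2 lists hold transcripts of hepatocytes: acute phase genes (11 of 12 positive, median 0.61, adjusted p = 0.754 with an estimated correlation) and the list of hepatocyte transcripts (16 of 20, median 0.23, adjusted p = 0.967 with an estimated correlation, and a median of -0.15 without the batch term). In the list of hepatocyte transcripts, Bhmt and Hp were higher (log2 1.95 and 1.095). Mup20 was lower, at 606 ± 251 and 285 ± 194 CPM (log2 -0.73). The immunoglobulin transcript Igkc, a product of plasma cells, stood at 16.5 ± 14.3 and 173 ± 122 CPM. It did not pass in the main fit and passed in 2 of 18 alternatives, among them the replicate block (log2 3.43). Of 8955 genes, edgeR called 3, all lower and all haemoglobin transcripts: Hba-a1 at 232 ± 37.7 and 16.9 ± 14.7 CPM (log2 -3.82, SE 0.42, adjusted p = 0.0286), Hbb-bs (-3.50, adjusted p = 0.0286) and Hba-a2 (-3.43, adjusted p = 0.0375). Hba-a1 and Hba-a2 are near-identical copies, so the share of each is uncertain. Of the haemoglobin UMIs in stellate cells of DMSO libraries, 90.9% lay in 4 barcodes (2, 1 and 1), and without barcodes of this kind the count of genes was 0. The count was also 0 without DMSO 1, DMSO 3, CWHM-12 2 or CWHM-12 3, and 7 without DMSO 2.

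In Kupffer cells, some markers of the macrophages that gather in liver scars were lower under CWHM-12, and so were genes of the cell cycle. The scar-associated list was negative in 11 of 18 genes, with a median of -0.11 and a mean of -0.46 (-0.051 and -0.43 as medians within the batches; adjusted p = 1.51e-07, and adjusted p = 0.443 with an estimated correlation). Its fall rests on few members, of which 3 passed when adjusted over the list alone and 0 over all genes. Cd63, which sits in late endosomes, stood at 29.3 ± 7.23 and 5.94 ± 2.88 CPM (log2 -2.08, SE 0.22), and was lower by -1.83 and -2.21 within the batches. In LSEC, Cd63 also had a negative log2 fold change, of -1.39, without passing. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, stood at 9.82 ± 2.20 and 1.06 ± 0.893 CPM, and Itgax, the integrin subunit CD11c, at 13.4 ± 1.35 and 5.05 ± 0.864 CPM. Each of the 3 genes was lower in every CWHM-12 library than in every DMSO library. Olfml3, a secreted olfactomedin family protein chosen after its values were seen, stood at 24.5 ± 5.92 and 6.37 ± 0.770 CPM. The cell cycle list was negative in 19 of 20 genes, with a median of -0.44 (-0.38 and -0.41 within the batches; adjusted p = 1.58e-05, and adjusted p = 0.770 with an estimated correlation). Cluster 30, led by genes of dividing cells such as Top2a and Mki67, held 4.34%, 4.44% and 5.65% of Kupffer cells in DMSO 1 to 3 and 5.05%, 5.32% and 2.87% in CWHM-12 1 to 3. Cluster 22, with Gpnmb among its leading genes and 411 cells, was left unnamed and is not part of this class.

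Genes of flow and stretch (11 of 12 positive, median 0.21), dissociation and early response (16 of 18, median 0.49) and the unfolded protein response (11 of 13, median 0.19) rose in Kupffer cells. Genes of the interferon response (19 of 24 negative, median -0.19) and collagens and matrix proteins (10 of 12, median -0.42) fell. These 5 calls had adjusted p-values of 0.635, 0.635, 0.770, 0.882 and 0.882 with an estimated correlation. Klf2 stood at 216 ± 32.5 and 734 ± 447 CPM (log2 1.29, SE 0.36), Jun, an immediate early transcription factor, at 308 ± 119 and 544 ± 143 CPM, and the TGF-β receptor Tgfbr1 at 105 ± 13.8 and 69.4 ± 3.23 CPM. The TGF-β response list (12 of 20 negative, median -0.12, adjusted p = 0.122) and Kupffer identity (11 of 15 positive, median 0.11, adjusted p = 0.137) did not pass. Itgav stood at 132 ± 12.2 and 114 ± 13.2 CPM. Over 11496 genes, edgeR called 0, with 202 at an unadjusted p under 0.05 and a smallest adjusted p of 0.416 for Cd63. DESeq2 called 3 (Cd63, Gpnmb and Olfml3) and limma voom 2 (Cd63 and Olfml3). Without DMSO 2, edgeR called 3 (Cd63, Olfml3 and the hepatocyte transcript Mup20). Cluster 2 has Trem2 of the scar-associated list among its leading genes, and cluster 0 has Kupffer markers such as Timd4 and Marco. Cluster 2 held 77.3%, 45.8% and 51.5% of Kupffer cells in DMSO 1 to 3. It held 73.1%, 17.4% and 9.58% in CWHM-12 1 to 3, and cluster 0 held most of the rest. Whether the scar-associated list fell through this mix of clusters was not tested. The mitochondrial share of UMIs in Kupffer cells was 9.91%, 10.9% and 8.59% in DMSO 1 to 3 and 8.78%, 7.40% and 7.82% in CWHM-12 1 to 3, lower under CWHM-12 within both batches, and the median UMIs per cell were 1751, 4288 and 3791 and 1967, 5952 and 8918.

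**Figure D3:**
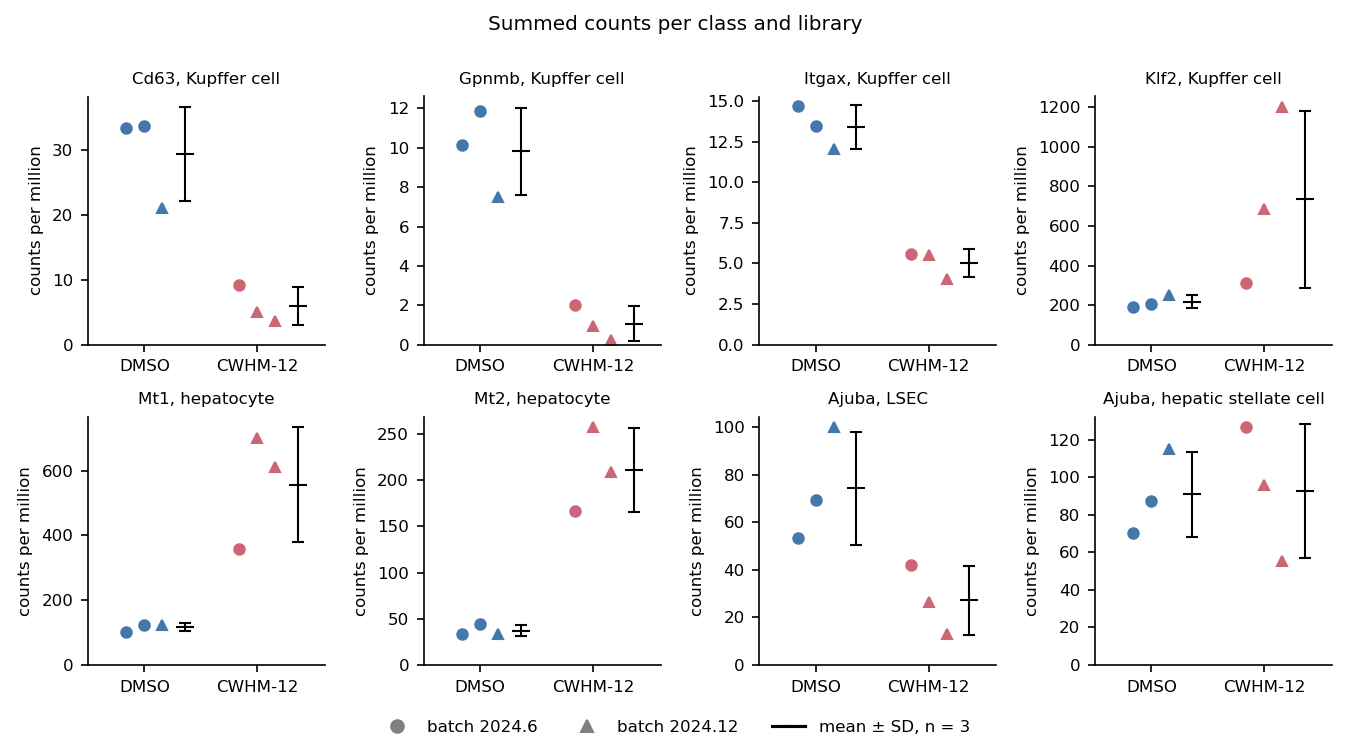
CPM (y axis, linear from 0) in each library for genes of Kupffer cells and hepatocytes and for Ajuba in LSEC and stellate cells; circles are libraries of batch 2024.6, triangles those of batch 2024.12, and black marks the mean ± SD of 3 libraries. Cd63 lies at 20.98 CPM or more in DMSO libraries and at 9.16 CPM or less in CWHM-12 libraries, and Mt2 in hepatocytes at 43.8 CPM or less and at 167 CPM or more.

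In monocytes and monocyte-derived macrophages, genes that mark Kupffer cells, another class of these livers, were higher under CWHM-12. All 11 measured genes of the Kupffer identity list were positive, with a median of 1.499 that differed between batches (0.55 and 4.28; adjusted p = 7.69e-07, and adjusted p = 0.595 with an estimated correlation). Clec4f, a lectin receptor of Kupffer cells, stood at 40.2 ± 33.6 and 359 ± 217 CPM, and the iron exporter Slc40a1 at 81.8 ± 30.7 and 418 ± 250 CPM. Lists of iron handling (10 of 10 positive, median 0.47), the unfolded protein response (10 of 11, median 0.54), dissociation and early response (10 of 14, median 0.45) and efferocytosis and lysosome (14 of 20, median 0.47) rose with it, with adjusted p-values of 0.803, 0.803, 0.595 and 0.982 with an estimated correlation. The median of efferocytosis and lysosome was -0.16 without DMSO 3 and -0.11 with classes from marker scores alone. Saa3, an acute phase protein of macrophages, stood at 0, 10.7 and 0 CPM in DMSO 1 to 3 and at 51.7, 424 and 418 CPM in CWHM-12 1 to 3. Ly6i, a surface protein of monocytes, stood at 149 ± 49.5 and 36.5 ± 19.3 CPM, and Itgav at 103 ± 26.5 and 112 ± 23.6 CPM. Over 4219 genes, edgeR called 0, with 99 at an unadjusted p under 0.05, DESeq2 called 1 (Saa3) and limma voom 0. Without DMSO 2, edgeR called Saa3 (adjusted p = 0.0329, against 1.60e-10 to 1 over its alternatives). CWHM-12 3, with 24 cells, had the lowest median correlation with the other libraries across genes (0.771). The class held 24 to 82 cells per library and 136973 to 693335 UMIs.

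In hepatocytes, the metallothioneins Mt1 and Mt2, which bind zinc and are induced by metals and glucocorticoids, stood higher in every CWHM-12 library than in every DMSO library, without passing the test. Mt2 stood at 36.9 ± 6.03 and 211 ± 45.3 CPM (log2 2.46, SE 0.34; 2.10 and 2.77 within the batches; edgeR adjusted p = 0.282) and Mt1 at 117 ± 12.1 and 557 ± 178 CPM. Tsc22d3, a glucocorticoid-induced leucine zipper protein, stood at 31.2 ± 11.8 and 57.2 ± 10.4 CPM. Itgav was lower without passing, at 19.9 ± 10.7 and 8.17 ± 1.71 CPM (log2 -1.005, and -1.44 and -0.252 within the batches). Genes of pericentral hepatocytes fell, with 10 of 14 negative and a median of -0.50 (-0.90 and 0.022 within the batches; adjusted p = 0.429 with an estimated correlation). Of these, Cyp2a5 stood at 453, 1509 and 642 CPM in DMSO 1 to 3 and at 267, 222 and 338 CPM in CWHM-12 1 to 3, and it is among the leading genes of cluster 32, which holds mainly cells of DMSO 2. In all, 19 of 34 lists passed, 18 of them lower, and many of these hold genes of stellate and endothelial cells. Collagens and matrix proteins had a median of -0.95 (11 of 11 negative, -1.35 and -0.11 within the batches), stellate cell quiescence -0.98 (15 of 16), endothelial capillarization -1.07 (12 of 12, -1.29 and -0.33 within the batches) and the TGF-β response -0.51 (15 of 18, -0.78 and -0.023 within the batches). With an estimated correlation, the adjusted p was 0.429 for these lists other than quiescence, at 0.439. Transcripts of stellate cells such as Reln stood at 161, 127 and 17.1 CPM in DMSO 1 to 3 and at 27.1, 17.6 and 8.10 CPM in CWHM-12 1 to 3. The mitochondrial share of UMIs in hepatocytes was 11.2%, 13.03% and 2.72% in DMSO 1 to 3 and 6.78%, 8.97% and 5.75% in CWHM-12 1 to 3, so in batch 2024.6, where these lists fell most, it was also lower under CWHM-12. Erythroid transcripts rose (6 of 6, median 0.47, adjusted p = 0.429 with an estimated correlation). Of 10314 genes, edgeR called 0, with 222 at an unadjusted p under 0.05, while DESeq2 and limma voom each called 2 and edgeR without DMSO 2 called 2, in each case Mt1 and Mt2. Cluster 32 held 50.6% of the hepatocytes of DMSO 2 and at most 0.0684% of those of any other library, cluster 9 held 57.9% of those of DMSO 3, cluster 16 held 27.99% of those of CWHM-12 1, and clusters 11 and 17 held 43.9% and 42.9% of those of CWHM-12 3.

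In the 9 other classes tested, edgeR called 3 genes, all higher in neutrophils under CWHM-12 and all known from endothelium: Ehd3 (log2 2.51, SE 0.50, adjusted p = 0.00977), Ptprb (2.70, SE 0.53, adjusted p = 0.00977) and Maf (2.54, SE 0.57, adjusted p = 0.0385). They rest on 5 libraries, since CWHM-12 3 held 2 neutrophils, and the genes were chosen after their values were seen. DESeq2 called 9 genes in these classes and 0 in neutrophils, and limma voom 1 in neutrophils. In neutrophils edgeR called 0 genes without DMSO 1, 0 without DMSO 2 and 0 without DMSO 3, and also 0 with the replicate block, with the looser cell filter, with classes from marker scores alone and with GC offsets. Summed over these classes, it called 190 without DMSO 2, of which 131 in mesothelial cells, 25 without DMSO 1, all in mesothelial cells, 7 without DMSO 3, and 0 without CWHM-12 1 or CWHM-12 2, where neutrophils could not be fitted. The most widespread list was dissociation and early response, which rose in 8 of 14 classes, with a median of 0.73 in macrovascular endothelium (17 of 17 positive), 0.36 in cholangiocytes (16 of 18) and 0.34 in T cells (12 of 14), and adjusted p-values of 0.689, 0.529 and 0.437 with an estimated correlation. The TGF-β response fell in T cells (8 of 11 negative, median -0.33, -0.20 and -0.45 within the batches, adjusted p = 0.00138, and 0.437 with an estimated correlation). It also fell in mesothelial cells, which cover the liver surface (13 of 20 negative, median -0.37, adjusted p = 4.94e-04, and 0.539 with an estimated correlation). CWHM-12 1, with 9 mesothelial cells, was left out, so with the batch term the contrast in this class rests on DMSO 3 alone, with 29 cells, against CWHM-12 2 and CWHM-12 3; the median was -0.29 without the batch term. Markers of LSEC identity rose in T cells (7 of 7, median 0.51, adjusted p = 0.437 with an estimated correlation) and in cholangiocytes (9 of 10, median 0.57, adjusted p = 0.529 with an estimated correlation), and these are transcripts of another cell type; in cholangiocytes the median was -0.073 without DMSO 3. Over the 14 classes 71 list calls passed, and 0 with an estimated correlation. Other groupings of the same libraries gave up to 86 list calls, against 63 for the real groups, in the classes that could be fitted in each grouping.

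Whether the response to CWHM-12 differs between LSEC and stellate cells was tested directly, and 2 of 11938 genes passed, with 853 at an unadjusted p under 0.05. For Ajuba, the log2 response of stellate cells exceeded that of LSEC by 1.54 (SE 0.19, edgeR adjusted p = 0.00681). In LSEC it stood at 53.4, 69.5 and 100.1 CPM in DMSO 1 to 3 and at 42.03, 26.6 and 12.8 CPM in CWHM-12 1 to 3, and in stellate cells at 70.5, 87.4 and 115 CPM and at 127, 96.2 and 55.7 CPM. The other gene, ENSMUSG00000120732, has no symbol, was chosen after its values were seen and went the other way (log2 -1.46, SE 0.21, adjusted p = 0.0356). Without DMSO 3 the count was 0 (adjusted p = 0.112 for Ajuba), without CWHM-12 1 it was 95, without CWHM-12 2 it was 8 and without DMSO 1 it was 5. With classes from marker scores alone it was 0.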

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

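The tests of GC content, depth, cell quality and the cells removed by the filter for DMSO 2, of CWHM-12 1 in genes chosen without it, of free haemoglobin RNA and of other groupings of the libraries were chosen after the result was seen. The response to CWHM-12 differed between stellate cells and LSEC by a test of the difference itself for Ajuba, by 1.54 on the log2 scale, and for ENSMUSG00000120732, by -1.46. Ajuba encodes a LIM domain protein of the Hippo pathway, and its CPM in LSEC was lower in each CWHM-12 library than in each DMSO library, while in stellate cells the groups overlapped.

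DMSO 2 lay apart from the other 5 libraries in LSEC, stellate cells, Kupffer cells and hepatocytes, where its median correlation with the others across genes was the lowest, at 0.922, 0.852, 0.933 and 0.768. Lower depth as the whole cause is argued against, since DMSO 2 stayed lowest in 4 of 4 classes after all libraries were thinned to 1 total. GC content bias as the whole cause stays open. DMSO 2 stayed lowest in 4 of 4 classes after GC offsets, at 0.943, 0.878, 0.951 and 0.788, but higher than before in each. The GC content was matched by symbol from another build, so the offsets may be incomplete. The cells that the stricter filter removes are argued against as the whole cause in stellate cells and hepatocytes. There the filter took 23.3% and 46.8% of the UMIs of DMSO 2. With libraries thinned to 1 total within each setting, its gap to the next library was at least 1.06 times that without the filter. The totals with and without the filter were not the same. Damage shared by the cells that remain stays open: DMSO 2 stayed lowest in 4 of 4 classes with this filter, at 0.920, 0.835, 0.932 and 0.676, but its mitochondrial share before it was the highest of the 6 libraries in each, at 11.2%, 12.3%, 10.9% and 13.03%. A part of the distance is consistent with GC content bias in this library, since its deviation correlated with the GC content of transcripts across genes at a median Spearman value of -0.521. Beyond these 4 classes, DMSO 2 also had the lowest median correlation in classes such as cholangiocytes (0.866), T cells (0.836) and macrovascular endothelium (0.862). In B cells and monocytes CWHM-12 3 had the lowest. No biological explanation was tested, and without DMSO 2 the counts of genes were 7 in stellate cells, 3 in Kupffer cells, 1 in monocytes and 2 in hepatocytes.

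LSEC of CWHM-12 2 and CWHM-12 3 lay in part in other clusters than those of DMSO 3, since cluster 5 held 39.2% in DMSO 3 and 4.08% and 0.405% in these, although clusters 7 and 8 held 22.5% and 11.5% in DMSO 3 and 28.3% and 30.8% in CWHM-12 2, while CWHM-12 1 lay near DMSO 1, with 49.1% and 44.5% in cluster 5. Low-quality cells stay open: the genes that differed most kept 1.01 of their difference with the stricter cell filter, but this filter left 93.2%, 96.8% and 94.6% of the LSEC UMIs of DMSO 3, CWHM-12 2 and CWHM-12 3, so it could hardly have come out otherwise. A wrong label of CWHM-12 1 stays open. The contrasts of the batches correlated by more than 0.2 across genes in 0 of the 5 main classes. Further, 100 genes were chosen by p in fits without CWHM-12 1, where DMSO 3 is the only control of its batch. In 40% of them (25% to 60% by class), CWHM-12 1 lay on the side of the other CWHM-12 libraries, which a response that differs between batches could also give. The side was taken against the mean of DMSO 1 and DMSO 2. Since DMSO 2 lay apart, its deviation may have set the side in part, so this share cannot decide the label. Values that go with the label of CWHM-12 1 are Mt2 in hepatocytes, at 167 CPM against 33.5 and 43.8 CPM in DMSO 1 and DMSO 2, and Cd63 in Kupffer cells, at 9.16 CPM against 33.4 and 33.6 CPM. But these genes were named from fits that count CWHM-12 1 as treated. A response that differs between batches and the treatment itself stay open as well: a batch by treatment term in edgeR called 0 genes in LSEC, with 452 at an unadjusted p under 0.05, and CWHM-12 1 is the only treated library of its batch.

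Haemoglobin transcripts, the 3 genes called in stellate cells, were lower in the CWHM-12 libraries. Free RNA at one level per library as the whole source is argued against, since the ratio of haemoglobin in stellate cells to that in LSEC differed 341-fold between libraries, from 0.0383 to 13.1, although haemoglobin in LSEC also lay in few barcodes and either class may have moved the ratio. A few stellate barcodes that hold an erythroid cell are a candidate source, since 90.9% of the haemoglobin UMIs in DMSO stellate barcodes lay in barcodes with at least 10. No biological explanation was tested.

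The 6 libraries form 10 groupings of 3 and 3, of which the grouping by batch could not be fitted with a batch term, so 9 remained. These are too few for a share under 0.05. In LSEC, Kupffer cells, monocytes and hepatocytes, the real grouping gave 0 genes and the highest of the others 0, so 9 of 9 gave as many. In stellate cells it gave 3 genes, the highest other 1, and 1 of 9 as many. In the other classes it gave 0 genes over the classes fitted in each grouping, the highest other 4, and 9 of 9 as many. The list calls numbered 63 in the real grouping and 86 in the highest other, DMSO 1, DMSO 3 and CWHM-12 2 against the rest, and 7 of 9 gave as many. For the difference between LSEC and stellate cells, the real grouping gave 2 genes, the highest other 0, and 1 of 10 as many.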

How the results depend on the processing

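GC offsets and the fit without barcodes rich in haemoglobin were added after the data were seen. Of 156 recomputed main counts, 109 stayed within 1.5 times the reported count and 47 moved. Of 1180 recomputed list medians of the 71 list calls, 899 kept their direction and passed, 257 kept their direction and no longer passed, and 24 turned in the direction given by camera. Of the 71 calls, 10 were kept in every alternative run. Among 16 alternatives, LSEC kept the call of periportal hepatocyte genes in 8 and of flow and stretch in 11. Kupffer cells kept that of collagens and matrix proteins in 9, and macrovascular endothelium that of flow and stretch in 9. Of 2959 values of named genes, 2832 kept direction and side of the threshold, 40 passed only in the alternative, 26 no longer passed, 60 moved and 1 was counted as reversed. The sign turned in more genes than that 1. Over the alternatives, H2-Ab1 in stellate cells ranged from -0.19 to 1.53 and Slc40a1 in monocytes from -0.34 to 3.38. Shares stayed within 1 SD in 207 of 223 cases. The cause of the changes below was not tested, except where a sentence names it.

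Without the filter on low counts, edgeR called 67 genes in LSEC, 28 in stellate cells, 19 in Kupffer cells, 13 in monocytes, 6 in hepatocytes, 291 in the other classes and 133 for the difference between LSEC and stellate cells, and 114 lists passed. DESeq2 called 3 genes in LSEC, 3 in Kupffer cells, 1 in monocytes, 2 in hepatocytes and 9 in the other classes. With limma voom and sample weights, 2 genes were called in Kupffer cells and 2 in hepatocytes. With the size factors of DESeq2, 1 gene differed between LSEC and stellate cells.

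In stellate cells the count was 0 with the looser cell filter, 0 with the stricter cell filter, 0 with the class by marker score, 0 with equal cells per library and 0 with barcodes rich in haemoglobin left out, where Hba-a2 had a log2 fold change of 0.29; this alternative removes the barcodes that hold those transcripts. In the other classes, neutrophils included, the count was 0 with the looser cell filter, 35 with the stricter cell filter (neutrophils could not be fitted), 0 with the class by marker score and 8 with equal cells per library. With the class by marker score, 0 genes differed between LSEC and stellate cells and 121 lists passed, and the median was -0.17 for MHC class II presentation in stellate cells and -0.11 for efferocytosis and lysosome in monocytes. With an estimated correlation 0 lists passed.

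With the replicate number as a block in place of the batch term, the counts were 0 in LSEC, 4 in stellate cells, 0 in Kupffer cells, 1 in monocytes, 0 in hepatocytes and 11 in the other classes, all 11 in mesothelial cells and 0 in neutrophils, with 68 lists and 0 shares. The block also gave medians of -0.25 for acute phase genes in B cells, 0.017 for hepatocyte transcripts in stellate cells and -0.86 for LSEC identity in plasmacytoid dendritic cells. Without the batch term the medians were -0.12 for hepatocyte transcripts in B cells, -0.15 for hepatocyte transcripts in stellate cells, -1.90 for LSEC identity in plasmacytoid dendritic cells and -0.26 for hepatocyte transcripts in plasmacytoid dendritic cells.

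With each library left out in turn, the counts ranged from 0 to 7 in stellate cells, 0 to 3 in Kupffer cells, 0 to 1 in monocytes, 0 to 2 in hepatocytes, 0 to 190 in the other classes, where neutrophils gave 0 without DMSO 1, DMSO 2 or DMSO 3, and 0 to 95 for the difference between LSEC and stellate cells. The highest came without DMSO 2, or without CWHM-12 1 for that difference. For the lists below, the direction by camera turned when a library was left out. Their median was lowest without DMSO 3 and highest without CWHM-12 1. It crossed 0 except for flow and stretch in macrovascular endothelium and stellate cell activation in hepatocytes. With the batch term, the fit without DMSO 3 rests on CWHM-12 1 against DMSO 1 and DMSO 2, the libraries of its batch. The fit without CWHM-12 1 rests on CWHM-12 2 and CWHM-12 3 against DMSO 3, the libraries of the other batch. Each extreme is thus the contrast within 1 batch, and does not show the weight of a single library. The medians ranged from -0.71 to 1.92 for pericentral hepatocyte genes in B cells, -0.27 to 1.56 for acute phase genes in B cells and -0.52 to 1.31 for hepatocyte transcripts in B cells. They ranged from -0.073 to 1.53 for LSEC identity in cholangiocytes, -0.12 to 0.75 for hepatocyte transcripts in stellate cells, 0.014 to 0.45 for flow and stretch in macrovascular endothelium, -0.16 to 0.85 for efferocytosis in monocytes and -0.73 to 2.16 for hepatocyte transcripts in NK cells. In hepatocytes they ranged from -0.77 to 0.087 for other integrin subunits, -0.72 to -0.080 for stellate cell activation, -0.79 to 0.33 for LSEC identity, -1.03 to 0.026 for leukocyte adhesion and -0.69 to 0.34 for efferocytosis. Where 1 library remains in a group of a batch, it is assumed to vary like the others.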

Other observations

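The lists below were fixed before their results were seen, the ones described were picked among those that passed, and the glucocorticoid test was chosen after the values of Mt1, Mt2 and Tsc22d3 were seen. In macrovascular endothelium, the cells that line portal and central vessels, genes of periportal endothelium rose under CWHM-12 (9 of 11 positive, median log2 fold change 0.73, 0.51 and 1.15 within the batches, adjusted p = 1.76e-04, and adjusted p = 0.689 with an estimated correlation). The class joins cluster 14, led by genes such as Rspo3 and Wnt9b, and cluster 21, led by genes such as Gja5 and Efnb1. Cluster 21 held 26.8%, 32.9% and 8.88% of the class in DMSO 1 to 3 and 25.3%, 42.1% and 83.8% in CWHM-12 1 to 3. Genes of flow and stretch (median 0.38, and 0.014 without DMSO 3) and of the NF-κB response (median 0.33) rose with them, each with an adjusted p of 0.689 with an estimated correlation. In cholangiocytes, genes of MHC class II presentation rose (6 of 6 positive, median 0.53, 1.06 and 0.23 within the batches, adjusted p = 0.568 with an estimated correlation), as did genes of efferocytosis and lysosome (16 of 17 positive, median 0.31, adjusted p = 0.529 with an estimated correlation). Whether the transcripts of these 2 lists came from other cells was not tested. In T cells, effector and exhaustion genes rose (9 of 12 positive, median 0.26, 0.39 and 0.25 within the batches, adjusted p = 0.437 with an estimated correlation). This call was kept in 9 of 16 alternatives. Cluster 31, led by genes of naive T cells such as Tcf7 and Lef1, held 20.8%, 29.2% and 35.6% of T cells in DMSO 1 to 3 and 15.4%, 20.2% and 16.04% in CWHM-12 1 to 3. In plasmacytoid dendritic cells, which sense nucleic acids and release interferon, genes of the interferon response rose (9 of 10 positive, median 1.04, adjusted p = 0.441 with an estimated correlation). CWHM-12 1, with 16 of these cells, was left out, so with the batch term this rests on DMSO 3 alone, with 26 cells, against CWHM-12 2 and CWHM-12 3, and no fit without DMSO 3 was made; the median was 0.61 without the batch term.

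Mt1, Mt2 and Tsc22d3 stood higher in hepatocytes of CWHM-12 libraries and are all induced by glucocorticoids, so a wider glucocorticoid response of hepatocytes was a hypothesis. Over 18 other glucocorticoid-induced genes the median log2 fold change was 0.034, with 10 higher and 8 lower, a range from -1.996 to 1.29, and medians of -0.29 and 0.31 within the batches. Camera gave a p of 0.784, and 0.858 with an estimated correlation. A rise of this list as a whole was thus not seen. The members spread widely, with Pdk4 at a log2 fold change of -1.996 and Ddit4 at 1.29. The medians within the batches had opposite signs, so a response of some genes or in a single batch stays open.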
